A study of Arabidopsis thaliana with 18 samples.

How the data were processed

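Gene expression was measured on 18 Affymetrix Arabidopsis arrays, 1 array per sample. Per the labels, soil-grown Arabidopsis thaliana seedlings of 3 genotypes were used: the accession Col-0 (WT) and the homozygous T-DNA insertion lines wrky72-1 and wrky72-2. Seedlings 2 weeks old were sprayed with a suspension of 30000 spores per ml of Hyaloperonospora isolate Noco2 (Hpa), the oomycete that causes downy mildew, or with water (mock). Aerial tissue was harvested at 96 h. Each of the 6 groups held 3 independent biological replicates. Per the labels' protocols, total RNA was extracted with TRIZOL and biotinylated cRNA was prepared from 8 ug of it.

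The deposited values are the intensity of each probe set on each array, on a linear scale and all above 0. Per the submitters' processing notes, RMA and limma were used, without versions. The scale and any filter were not stated. The near-equal quartiles of all arrays show that the values had been normalised between arrays, so no further normalisation was applied and log2 was taken before any test. The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which left 22746. RMA as a method compresses changes near the background, so changes of weakly hybridising probe sets can be understated.

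The probe table gave exactly 1 gene for 13513 of the tested probe sets, several genes for 503 and none for 8730. These 13513 probe sets cover 13355 genes, of which 147 had more than 1 probe set. For those genes the probe set with the highest mean over the 18 arrays was used. Of the 13513 probe sets, 13436 were found in the RefSeq gene table by gene identifier and 77 were not. Probe sets with several genes or none were counted in every total but were not assigned to a gene. WRKY72, PR1, PR2, PR5, ICS1 and PAD3 had no probe set with a name and were not analysed here as genes. Positions in the genome were not analysed here.

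All comparisons came from 1 limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 6 groups, fitted to all 18 arrays. The model had 12 residual degrees of freedom, and the moderated variances added 7.79. Contrasts were the response to Hpa in each genotype (infected minus mock), the interaction of each mutant (its response minus the WT response), the interaction of both mutants (the mean of their responses minus the WT response), the difference between the mutants' responses, and each mutant against WT and against the other within each treatment. Tests were two-sided. P values were adjusted by Benjamini and Hochberg over the 22746 probe sets within each contrast, and an adjusted p under 0.05 counted as a call. The study's design counts as WRKY72-dependent the genes regulated in Col-0 and not in the mutants, so probe sets called in WT and in neither mutant were counted, each with its interaction. The number of arrays limits the precision: the median standard error of a log2 change was 0.10 for a response, 0.13 for the interaction of both mutants and 0.15 for the interaction of a single mutant.

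Before the data were examined, the contrasts, the threshold, the alternatives and 18 gene lists were fixed, together with the rule by which genes were named. Under that rule WRKY72, PR1, PR2, PR5, ICS1, PAD3 and PDF1.2 were to be named always. For each response the rule takes the 10 highest and the 10 lowest changes among called genes whose 3 infected arrays all lie outside the range of the 3 mock arrays, and for each interaction and genotype contrast the 10 highest and the 10 lowest called values. Where nothing was called, the 3 lowest p values on each side are named and said not to pass. For each list it takes the 4 called members with the largest absolute change, or the 1 largest if none is called. Of the genes called in WT and in neither mutant, it takes the 10 with the lowest interaction p. The text may name fewer, dropping from the smallest change up. Genes said to have been chosen after their values were seen fall outside the rule.

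Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Symbols in the probe table covered only 41 of the 317 entries of the planned lists. Hence 26 further lists with 458 entries, 453 of them measured, were drawn up from gene symbols after the probe table was seen. These added lists were chosen after results had been seen, so their p values do not test predictions made in advance. They were adjusted apart from the planned lists. Lists with under 3 measured members were not tested. List means are unweighted means of the members' log2 changes. Some added lists contain planned ones: the 4 measured members of the salicylic acid list, the 4 of the endoplasmic reticulum list, the 7 of the photosynthesis list and the 4 of the cold and drought list recur in larger lists.

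The size of the response was compared between WT and each mutant over probe sets called in the other mutant, so that neither compared genotype chose them. Because the mutants share differences from WT, this choice can favour them, and probe sets called in the mean of the WT response and the mean mutant response were used as well, chosen after the data were seen. Both mutants were compared with the same 3 WT arrays of each treatment. The correlation that this alone produces was measured on 20 simulated sets of unchanged groups.

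The model was tested on simulated data with known changes. Of 67 probe sets changed by a log2 of 0.5, it recovered 79.1% in the WT response, 52.2% in the interaction of both mutants and 29.9% in the difference between the mutants' responses. At a log2 of 1 the shares were 100%, 98.5% and 95.5%. Between 2.34% and 5.58% of the calls were false. In a test of camera on simulated lists of 20, a shift of 0.3 gave a p of 9.02e-21, and 1 of the unshifted lists fell under 0.05.

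The other settings tried were the replicate number as a fixed block or a random block, quantile normalisation applied again, array medians set equal, removal of the lowest 30% of probe sets by mean, only probe sets with 1 gene, a variance trend with robust moderation, array weights, a fit of only the groups compared, a log2 change of at least 1, an adjusted p under 0.01, and leaving out each array in turn or each replicate number from every group. For the probe sets called in WT alone, the mutants' limit was also set at an adjusted p over 0.2 or at a log2 change under 0.5, and each mutant was put in the place of WT. For lists, camera with the block and fry were also run, and for the response size a slope through the origin. Replicate numbers were checked by the correlation of same-numbered arrays' deviations from their group means. Of the pairs of groups, only infected wrky72-1 and infected wrky72-2 had every same-number correlation above 0.1 (0.269, 0.330 and 0.435), and each array correlated best with its own number. This pair was picked from all pairs of groups on these values, and the deviations of 3 arrays are not independent. A pairing of these arrays is thus possible and not established, and the labels do not give one. The mean of the hybridisation controls as a covariate, a replicate block for these 2 groups, the GAPDH difference between 3' and 5' control sets as a covariate and a fit without replicate 3 of the infected mutants were added after the data were seen. No column of the table was left unused.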

Results

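Transcript levels were measured in the aerial tissue of Arabidopsis seedlings of WT (Col-0) and of the insertion lines wrky72-1 and wrky72-2 at 96 h after spraying with spores of the downy mildew oomycete Hpa Noco2, which can grow on Col-0, or with water. WRKY72 is a gene of the WRKY family of plant transcription factors. Each of the 6 groups held 3 arrays. The median intensity of an array was between 34.1 and 37.1, the upper quartile between 141 and 162 and the highest value between 14520 and 16459, so the arrays were alike in signal. Group levels are given as mean log2 intensity ± SD (n = 3), log2 changes and differences as ± standard error from limma, and p values of genes are adjusted over all tested probe sets.

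Infection gave the largest difference between arrays, and genotype the next. Across probe sets, log2 intensities correlated at r 0.990 to 0.998 within a group and at 0.954 to 0.977 between mock and infected arrays; these correlations are across probe sets, which are not independent replicates. No arrays were identical. The first principal component, with 70.4% of the variance, parted mock from infected arrays in every genotype. The second, with 7.36%, parted all WT arrays, at -18.4 to -14.4, from all mutant arrays, at 4.49 to 14.3, and arrays of the mutants were intermixed on it. The median probe set was higher in infected than in mock arrays by a log2 of 0.09 in WT, 0.08 in wrky72-1 and 0.08 in wrky72-2, under the deposited scaling.

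**Figure D1:**
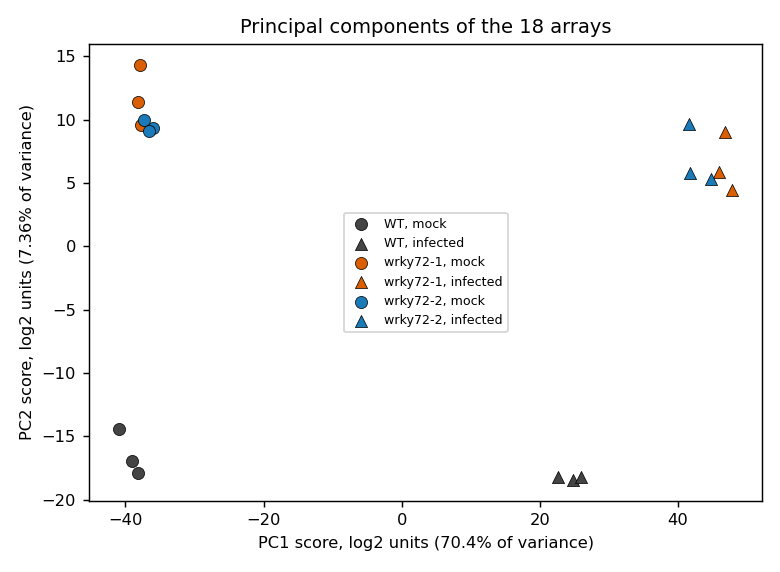
Scores of the 18 arrays on the first (70.4% of the variance) and second (7.36%) principal components of log2 intensity; circles are mock arrays, triangles infected arrays, and colours give the genotype. Infection separates the arrays along the first component, where infected mutant arrays lie farther from the mock arrays than infected WT arrays do. WT, at -18.4 to -14.4, separates from both mutants along the second.

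The WT response is the reference against which dependence on WRKY72 was to be judged. In infected WT seedlings lipid transfer protein and peroxidase genes were among those with the highest increases. The lipid transfer protein family genes AT4G12500 and AT4G12490 rose by log2 5.21 ± 0.14 (adjusted p = 4.9e-16) and 4.82 ± 0.11, the former from 5.38 ± 0.37 to 10.59 ± 0.16. The peroxidase genes AT5G64120 and Prx37 rose by 4.04 ± 0.08 and 3.26 ± 0.17, and STZ, a zinc finger transcription factor of stress responses, rose by 4.01 ± 0.09 (adjusted p = 1.6e-17). AT2G17740 rose by 4.02 ± 0.11, AT3G46280 by 3.9 ± 0.12, AT3G10930 by 3.78 ± 0.31, AT4G29780 by 3.48 ± 0.10 and AT5G52760 by 3.40 ± 0.13. PDF1.2, a defensin gene of the jasmonate and ethylene pathways, rose by 1.97 ± 0.09 (adjusted p = 2.8e-13), from 8.75 ± 0.15 to 10.72 ± 0.11.

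Decreases in WT were smaller. The largest among named genes were those of AT5G57785 (-1.87 ± 0.11), AT4G37220 (-1.80), AT3G53250 (-1.80), AT5G01015 (-1.71), AT4G12980 (-1.68), AT5G14410 (-1.67) and AT5G55620 (-1.66). The thionin gene THI2.2 fell by 1.61 ± 0.08 on the log2 scale. In total 7378 probe sets changed in WT, 3973 up and 3405 down, and named genes made up 1856 and 2046 of them. A change of at least 1 on the log2 scale was reached by 869 up and 211 down. With array medians set equal the split moved to 3154 up and 6228 down, so the balance of small changes depends on the scaling.

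Genes of salicylic acid defence rose together in WT. All 4 measured members of the planned salicylic acid pathway list rose, and 4 were up adjusted over the list alone, with a mean of 1.75 (camera adjusted p = 2.26e-07, adjusted p = 0.00477 with an estimated correlation). They were AT5G52810 at 2.29 ± 0.10, the glycosyltransferase gene UGT76B1 at 1.99 ± 0.11, the glutaredoxin gene GRX480 at 1.89 ± 0.12 and the lipase-like SAG101 at 0.82 ± 0.16. Of 7 measured WRKY genes 4 rose, and 5 were up and 1 down adjusted over the list alone. The mean was 1.12 and the median 0.50 (adjusted p = 4.37e-05 and 0.00694 with an estimated correlation). WRKY53 rose by 3.03 ± 0.12, WRKY6 by 2.21 ± 0.11, WRKY47 by 1.62 ± 0.19 and WRKY22 by 0.50 ± 0.11. All 4 measured members of the endoplasmic reticulum folding and secretion list rose, also 4 adjusted over the list alone, with a mean of 0.94 (adjusted p = 1.05e-05 and 0.00356 with an estimated correlation). The chaperone genes ATERDJ3B and CRT1b rose by 1.39 ± 0.09 and 1.02 ± 0.07, AT5G07340 by 0.90 ± 0.13 and the transcription factor gene BZIP60 by 0.43 ± 0.09.

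The other planned lists did not move as groups in WT. The cold and drought list split, with COR15A at -1.11 ± 0.07 and COR15B at -0.82 ± 0.07 down and LTI30 at 0.62 ± 0.14 and COR47 at 0.43 ± 0.09 up (2 and 2 adjusted over the list alone, mean -0.22, adjusted p = 0.484). Of 7 photosynthesis genes PSBY alone fell, by 0.21 ± 0.07, and 0 changed adjusted over the list alone (mean -0.10, adjusted p = 0.484). None of the 3 root markers passed, also adjusted over the list alone, and PYK10 had the largest value at 0.26 ± 0.12 (mean -0.05, adjusted p = 0.984). Lists with fewer measured members were not tested: the defensin gene PDF1.2b (1.63 ± 0.08), the kinase gene BIK1 (1.37 ± 0.09) and the clock gene GI (0.37 ± 0.10) rose, and SAG29 (-1.30 ± 0.12) and AUR1 (-0.31 ± 0.10) fell. THI2.1 (-0.06 ± 0.10), EFR (0.33 ± 0.15), ATHSP22.0 (-0.08 ± 0.10), FMA (0.19 ± 0.12) and the chromosomal neighbours of WRKY72, AT5G15110 (0.13 ± 0.08) and AT5G15140 (-0.18 ± 0.10), did not pass. Lists of tryptophan and camalexin synthesis, intracellular immune receptors and flower markers had no named probe set.

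Of the 26 added lists, which were chosen after results had been seen, 9 moved in WT, and 4 of them also with an estimated correlation. Of 25 early immune signalling genes 17 rose and 1 fell (mean 1.05, adjusted p = 2.0e-13 and 8.4e-05 with an estimated correlation), with STZ, WRKY53 and the calmodulin-like CML38 (2.50 ± 0.18) highest. Of 11 salicylate and systemic immunity genes 9 rose (mean 1.25, adjusted p = 6.5e-12 and 8.4e-05 with an estimated correlation), among them RING1 at 1.77 ± 0.09. Of 11 jasmonate genes 6 rose (mean 0.82, adjusted p = 7.9e-06 and 0.0027 with an estimated correlation), with JRG21 at 1.94 ± 0.11, OPCL1 at 1.55 ± 0.10 and ORA47 at 1.42 ± 0.11. Of 15 genes of endoplasmic reticulum folding and degradation 9 rose (mean 0.47, adjusted p = 7.5e-06 and 0.0018 with an estimated correlation), including BZIP28 at 0.90 ± 0.09.

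The calls of the other 5 of these lists were lost with an estimated correlation. Nuclear photosynthesis genes were lower, 9 of 24 down and 1 up, with NdhL at -1.10 ± 0.16 and TAPX at -1.0 ± 0.10 (mean -0.25, adjusted p = 0.0109, adjusted p = 0.0594 with an estimated correlation). SWEET sugar transporters were lower, 6 of 14 down and 1 up, with SWEET16 at -1.45 ± 0.14 (mean -0.34, adjusted p = 0.0392, adjusted p = 0.075 with an estimated correlation). Of 15 genes of exocytosis 6 were higher, with KEU at 0.83 ± 0.13 (mean 0.24, adjusted p = 0.0278, adjusted p = 0.075 with an estimated correlation). Of 18 CYP71B cytochromes P450 6 were higher, with CYP71B23 at 2.89 ± 0.19 (mean 0.40, adjusted p = 0.0278, adjusted p = 0.0594 with an estimated correlation). Of 47 UDP-glycosyltransferases 12 were higher and 4 lower, with UGT87A2 at 2.11 ± 0.11 (mean 0.21, adjusted p = 0.0278, adjusted p = 0.257 with an estimated correlation).

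The remaining added lists were not called in WT, and their means and adjusted p values are given in parentheses in that order. Of 69 chloroplast-encoded genes 6 rose and 12 fell (mean -0.12, adjusted p = 0.513), with petL at -1.20 ± 0.31 and the ribosomal protein gene rpl22 at 1.11 ± 0.19. Of 18 expansins 1 rose and 6 fell (mean -0.17, 0.164), of 15 tetraspanins 2 and 7 (-0.15, 0.165), of 19 auxin genes 2 and 5 (-0.04, 0.753), of 29 serine carboxypeptidase-like genes 4 and 5 (0.07, 0.353) and of 10 autophagy genes 2 and 3 (-0.19, 0.345). STOMAGEN, a stomatal development signal, fell by 1.17 ± 0.09 and MUTE by 0.26 ± 0.09 among 4 guard cell lineage genes (-0.35, 0.202). Of 8 flavonoid genes 2 fell (-0.21, 0.202), of 7 iron genes 1 (-0.09, 0.62), and of 11 pollen markers 1 (-0.05, 0.814). Of 20 beta-glucosidases 5 rose (0.22, 0.0565) and of 8 leucine breakdown genes 3 (0.16, 0.161). Both directions were found among 9 xyloglucan endotransglucosylases with 2 up and 1 down (mean 0.04, median -0.11, 0.799), 9 tetrapyrrole genes with 2 and 2 (mean -0.02, median 0.01, 0.993), 11 dehydration genes with 2 and 2 (-0.09, 0.796), 17 mitosis genes with 3 and 1 and 14 glutathione S-transferases with 1 and 2 (-0.02, 0.993). For the mitosis genes (mean -0.003, 0.796) and the glutathione S-transferases the test pointed up while the mean was negative. The sign of the mean turned under a rescaling for the xyloglucan endotransglucosylases, the carboxypeptidase-like genes and the pollen markers.

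Both mutants responded to infection, with many of the same genes as WT. AT4G12490 rose by 5.07 ± 0.11 in wrky72-1 and 4.67 in wrky72-2, AT4G12500 by 4.8 and 4.76, and AT5G52760 by 4.62 and 4.52. Several genes rose by more than in WT: the oxidoreductase family genes AT1G26390 (4.09 ± 0.10 and 3.61) and AT1G26380 (3.62 and 3.61), the methyltransferase gene CCOAMT (3.75 and 3.68) and the chitinase family gene CHI (3.58 ± 0.09 and 3.73). The lowest changes were those of the nitrate transporter family gene AT3G21670 (-2.70 ± 0.09 in wrky72-1 and -2.61 in wrky72-2), AT4G12980 (-2.07 and -2.45), AT1G13650 (-2.30 and -2.18) and AT3G53250 (-2.10 and -2.16), and COR15A fell by 1.92 ± 0.07 in wrky72-1. PDF1.2 rose by 1.15 and 1.3. In wrky72-1 10308 probe sets changed, 4581 up and 5727 down, and in wrky72-2 8501, 4034 up and 4467 down. A change of at least 1 was reached by 1155 up and 460 down in wrky72-1 and by 962 up and 526 down in wrky72-2. With array medians set equal the splits were 3939 up and 8792 down, and 3321 up and 5917 down.

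The salicylic acid and endoplasmic reticulum lists rose in both mutants as in WT, each with all 4 members up, also adjusted over the list alone. The salicylic acid list had means of 1.99 in wrky72-1 (camera adjusted p = 8.9e-07) and 1.89 in wrky72-2 (1.9e-06), and the endoplasmic reticulum list 0.98 (3.5e-05) and 1.0 (3.3e-05). Of the 7 WRKY genes 4 rose and 1 fell in wrky72-1 and 5 rose and 1 fell in wrky72-2, as they did adjusted over the list alone, with means of 0.91 (adjusted p = 0.0064 and 0.046 with an estimated correlation) and 0.98 (0.0048 and 0.04). The cold and drought list, which split in WT, fell in the mutants, with all 4 members down, also adjusted over the list alone, and means of -1.01 in wrky72-1 (adjusted p = 0.00042 and 0.038 with an estimated correlation) and -1.01 in wrky72-2 (3.3e-05 and 0.017). Leucine breakdown genes rose, 7 of 8 with a mean of 0.51 in wrky72-1 (adjusted p = 0.0001 and 0.01 with an estimated correlation) and 6 of 8 with 0.43 in wrky72-2 (0.0015 and 0.022). The chloroplast-encoded list was lower in wrky72-2, 36 of 69 down and 3 up with a mean of -0.43 (adjusted p = 3.3e-05, adjusted p = 0.52 with an estimated correlation). In wrky72-1 its mean change was -0.01. The mean level of the chloroplast-encoded probe sets was 9.65, 9.54 and 9.05 in the infected wrky72-2 arrays, the last being replicate 3, which weighed on the change. It was 9.85 in mock wrky72-2 and 9.64 in mock WT. Within groups, deviations of these transcripts went with those of the 25S rRNA control over the 18 arrays (r 0.776, permutation p = 0.00479, two-sided, and rho 0.736, p = 0.0059). In all 3 genotypes 2681 probe sets rose and 2097 fell, and 853 rose and 1382 fell in both mutants without a call in WT. Across probe sets the responses correlated at r 0.823 between WT and wrky72-1, 0.802 between WT and wrky72-2 and 0.934 between the mutants. The shared increases were 3008, 2817 and 3540 where independence would give 800, 705 and 812, and the shared decreases 2561, 2294 and 3584 where it would give 857, 669 and 1125.

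The size of the change depended on how the probe sets were chosen. Over probe sets chosen in one mutant, the median was larger in the other mutant than in WT. This choice favours the mutants wherever they share a difference from WT. Over the 4581 probe sets raised in wrky72-1, the median was 0.43 in WT and 0.53 in wrky72-2, and over the 4034 raised in wrky72-2 it was 0.48 in WT and 0.67 in wrky72-1. Over the 5727 lowered in wrky72-1 it was -0.24 in WT and -0.39 in wrky72-2, and over the 4467 lowered in wrky72-2 it was -0.30 in WT and -0.49 in wrky72-1. The change was larger in the mutant for 64.9%, 73.4%, 61.2% and 73.2% of the probe sets in these sets, in that order. For the set raised in wrky72-2, the mean over it of each infected array against its mock group was 0.64 ± 0.03 in WT and 0.85 ± 0.02 in wrky72-1 (SD, n = 3), and for the set lowered there -0.33 ± 0.02 and -0.55 ± 0.04. A slope of the mutant's changes on those of WT, which weights large changes, was 1.03 and 1.12 for the raised sets and 0.967 and 0.982 for the lowered sets, so the direction turned for the lowered sets. Over sets chosen in WT, a choice that favours WT, the medians of the mutants were 0.61 in wrky72-1 and 0.53 in wrky72-2 for raised and -0.46 and -0.45 for lowered probe sets, against 0.56 and -0.45 in WT itself. Over probe sets called in the mean of the WT and the mutant responses, the medians of WT, wrky72-1 and wrky72-2 were 0.42, 0.53 and 0.46 for 5412 raised and -0.28, -0.39 and -0.35 for 6661 lowered ones. The slopes on WT there were 1.05 and 1.03 in wrky72-1 and 0.972 and 0.986 in wrky72-2, so a larger response as such is not claimed.

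Genes regulated in WT and not in the mutants were the ones the study set out to find. AT5G17350 had the largest WT change among those named: it rose in WT from 4.68 ± 0.03 to 6.91 ± 0.30, a change of 2.23 ± 0.12, and its values were 5.32 and 5.55 in mock and infected wrky72-1 and 5.20 and 5.51 in wrky72-2 (interaction -1.96 ± 0.15, adjusted p = 1.9e-08). AT2G15780 rose in WT by 1.79 ± 0.12 (interaction -1.63), AT2G27080 by 1.56 (-1.31), AT1G11210 by 1.44 (-1.51), AT1G33600 by 1.41 (-1.49), AT2G28400 by 1.39 (-1.30), AT3G19030 by 1.32 (-1.47), AT1G15010 by 1.31 (-1.47) and AT5G61820 by 1.09 (-1.12). AT2G47880 fell by 1.22 in WT (interaction 1.37). AT1G11210 was already higher in mock-treated mutants than in mock WT, by more than its rise in WT. The rule thus does not tell a missing rise from a level already raised without infection. In total 1265 probe sets were called in WT and in neither mutant, 637 up and 628 down. Most of their WT changes were small: the median was 0.40 for raised and -0.32 for lowered sets, against 0.08 and -0.13 in wrky72-1 and 0.07 and -0.07 in wrky72-2, and 26 reached 1, 22 up and 4 down. The interaction passed for 355 of the 1265 (28.1%), 260 of the raised (40.8%) and 95 of the lowered (15.1%), all with the smaller change in the mutants. In 736 (58.2%) the values of both mutants had the sign of the WT change without a call. The same rule gave 2337 probe sets called in wrky72-1 alone and 986 in wrky72-2 alone. Without replicate 2 of infected WT, 838 were called in WT and in neither mutant.

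The interaction tests the difference between the responses itself. CHI rose by 2.12 ± 0.12 more in the mutants (adjusted p = 1.3e-10): it started lower, at 7.08 ± 0.13 in wrky72-1 and 7.08 ± 0.19 in wrky72-2 against 8.94 ± 0.10 in WT, and reached 10.66 ± 0.05, 10.81 ± 0.07 and 10.47 ± 0.06. AT1G26390 also started lower and rose by more (2.04 ± 0.12). AT3G02480 fell in WT (-0.68 ± 0.10) and rose in the mutants (1.40 and 1.33, interaction 2.04 ± 0.12). AT2G44240 (1.66 ± 0.17), the beta-glucosidase gene BGLU46 (1.53 ± 0.17), AT5G38910 (1.51), CCOAMT (1.35), AT1G19960 (1.34) and AT3G48650 (1.33) followed. On the other side STZ rose less in the mutants (interaction -2.81 ± 0.11, adjusted p = 5.5e-13): it went from 6.80 ± 0.11 to 10.81 ± 0.02 in WT, from 9.03 ± 0.02 to 10.23 ± 0.07 in wrky72-1 and from 9.01 ± 0.05 to 10.20 ± 0.18 in wrky72-2. AT3G21670 was at 8.14 ± 0.12 and 8.33 ± 0.09 in mock and infected WT and went from 9.11 to 6.41 and from 9.12 to 6.52 in the mutants (interaction -2.85 ± 0.11). AT3G10930 (-2.86 ± 0.37), AT4G27657 (-2.81 ± 0.23), AT4G27652 (-2.72 ± 0.15), AT4G29780 (-2.66), AT2G39980 (-2.58), AT2G22880 (-2.53), AT5G62280 (-2.18) and AT4G27654 (-2.03) also had a lower response in the mutants.

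**Figure D2:**
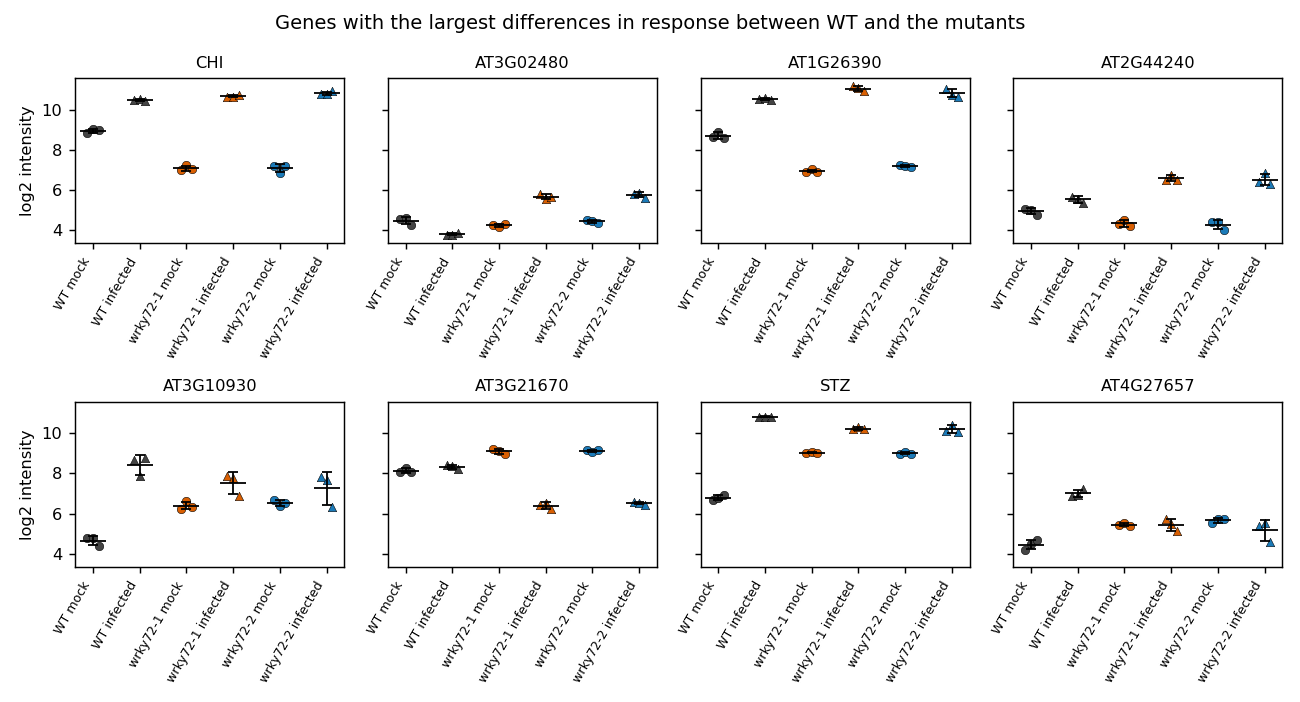
Log2 intensity of each array, with the mean and SD of each group (n = 3), for the 4 named genes with the highest and the 4 with the lowest interaction of both mutants. CHI and AT1G26390 start lower in mock mutants, STZ starts higher, and AT3G21670 falls in both infected mutants.

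The interaction of both mutants was called for 2995 probe sets, 1091 higher and 1904 lower, that of wrky72-1 for 2488, 995 and 1493, and that of wrky72-2 for 2155, 690 and 1465. At a size of at least 1, 97 were higher and 211 lower. Both single interactions were called in the same direction for 470 higher and 1039 lower. With quantile normalisation applied again, the splits were less uneven, at 1342 higher and 1571 lower for both mutants, 1185 and 1300 for wrky72-1 and 899 and 1207 for wrky72-2. A measure of RNA integrity, the log2 difference between the 3' and 5' control sets of a plant transcript, moved with the interaction for GAPDH (0.35 ± 0.11) and was 0.01 ± 0.08 for actin and -0.03 ± 0.07 for ubiquitin. With the GAPDH difference as a covariate, 1613 of the 2995 were called again, with a median size of 0.55 against 0.56 and a median standard error of 0.16 against 0.13, and without replicate 3 of the infected mutants, where that difference was highest, the interaction of both mutants was called for 3414.

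The interaction took several forms. In 700 of the 2995 probe sets the transcript rose in WT and rose less or fell in the mutants, with medians of 0.62 in WT and 0.02 in the mutants. In 201 it fell in WT and fell less or rose in the mutants (-0.61 against -0.12). In 518 it rose in WT and rose more in the mutants (0.89 against 1.55), and in 329 it fell in both and more in the mutants (-0.47 against -1.09). No change was called in WT for 372 with a higher change in the mutants (0.06 against 0.57) and for 875 with a lower one (0.01 against -0.54).

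Gene lists differed in the direction of their interaction. The cold and drought list had a lower response in the mutants, with LTI30 at -1.22 ± 0.18, COR47 at -1.19 ± 0.10 and COR15A at -0.73 ± 0.08 (mean -0.79, 3 of 4 down, and 3 adjusted over the list alone, camera adjusted p = 6.93e-06 and 0.0235 with an estimated correlation). Early immune signalling genes had a lower one, 11 of 25 down and none up, with CML38 at -1.54 ± 0.22, EXO at -1.18 ± 0.16 and WRKY22 at -1.15 ± 0.14 beside STZ (mean -0.42, adjusted p = 7.66e-05 and 0.0133 with an estimated correlation). Under infection camera called neither of these lists in either mutant against WT, while both were higher in mock mutants. In infected wrky72-1 the cold and drought mean was -0.19 (camera adjusted p = 0.584). The early immune mean there was 0.05, with 7 up and 6 down (camera adjusted p = 0.452). Jasmonate genes had a lower response, 4 of 11 down, with ORA47 at -1.83 ± 0.14, PDF1.2b at -0.85 ± 0.10, PDF1.2 at -0.75 ± 0.10 and OPCL1 at -0.55 ± 0.12 (mean -0.35, 0.00423 and 0.037 with an estimated correlation). Their mean in infected wrky72-1 against WT was -0.16 and was not called (camera adjusted p = 0.425). The cell wall enzymes XTH19 (-1.48 ± 0.15), XTH18 (-1.19 ± 0.13), XTH16 (-1.08 ± 0.16) and XTH32 (-0.82 ± 0.15) were the 4 of 9 xyloglucan endotransglucosylases that were lower (mean -0.52, 0.000791 and 0.0144 with an estimated correlation). Salicylate and systemic immunity genes had a higher response, 4 of 11 up: CHI, AT5G55450 (0.97 ± 0.09), RING1 (0.89 ± 0.11) and GRX480 (0.60 ± 0.14), with a mean of 0.45 (adjusted p = 0.000791 and 0.0144 with an estimated correlation). Against WT, however, camera called this list in neither infected mutant. Its mean was 0.11 in infected wrky72-1 (camera adjusted p = 0.2) and -0.35 in mock wrky72-1. Leucine breakdown genes were higher, with ETFBETA at 0.64 ± 0.15, ETFQO at 0.62 ± 0.10 and MCCA at 0.45 ± 0.09 (mean 0.30, 3 of 8 up, adjusted p = 0.00216 and 0.037 with an estimated correlation).

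The interaction of 5 further added lists was called with the preset correlation and lost with an estimated one. Autophagy genes had a mean of 0.28 with 2 of 10 up (adjusted p = 0.00423, adjusted p = 0.35 with an estimated correlation), and beta-glucosidases 0.20 with 3 of 20 up (0.0237, adjusted p = 0.0549 with an estimated correlation). Dehydration proteins had a mean of -0.39 with 4 of 11 down (0.000791, adjusted p = 0.0851 with an estimated correlation), glutathione S-transferases -0.22 with 4 of 14 down, led by GSTU20 at -0.94 ± 0.13 (0.0267, adjusted p = 0.0633 with an estimated correlation), and expansins -0.22 with 5 of 18 down, led by EXLA1 at -1.57 ± 0.11 (0.0362, adjusted p = 0.139 with an estimated correlation). Among planned lists the salicylic acid list (mean 0.19, adjusted p = 0.435, 1 of 4 up, and 1 adjusted over the list alone), the WRKY list (-0.17, 0.435, 1 of 7 down, and 2 adjusted over the list alone), photosynthesis (-0.08, 0.435), the endoplasmic reticulum list (0.06, 0.539, with 1 of 4 up, BZIP60 by 0.37 ± 0.12, and 1 adjusted over the list alone) and root markers (0.12, 0.539) were not called. No photosynthesis gene or root marker had a called interaction, also adjusted over the list alone, and their largest values were PSBY at -0.17 ± 0.09 and EXPA18 at 0.25 ± 0.21.

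**Figure D3:**
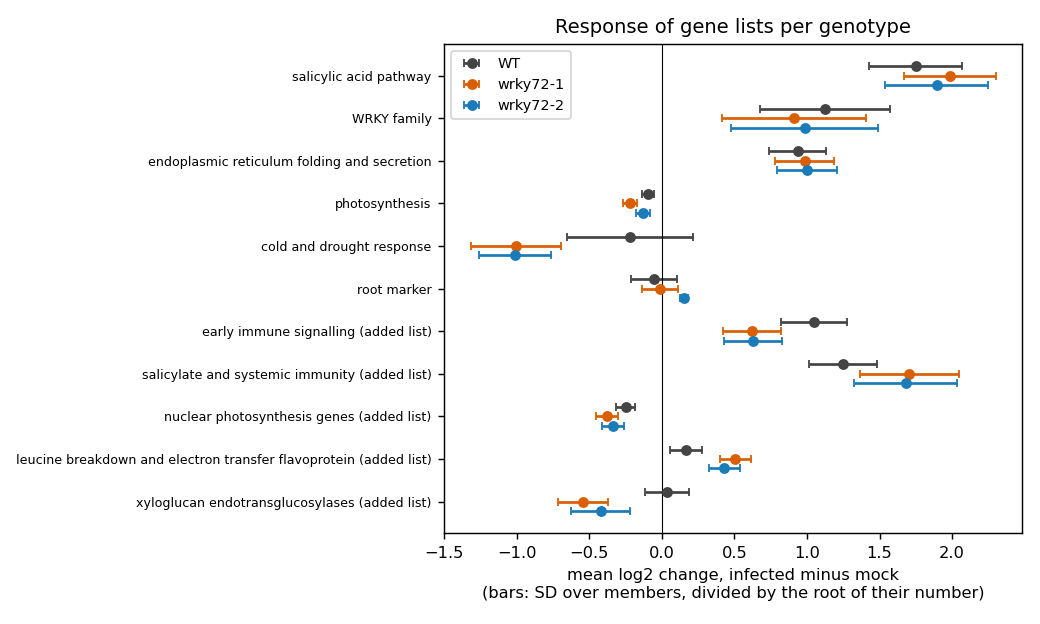
Mean log2 change, infected minus mock, of the members of 11 gene lists in each genotype; bars are the SD over members divided by the root of their number. The cold and drought list lies at -0.22 in WT and at -1.01 in both mutants, and early immune signalling, at 1.05 in WT, lies lower in both mutants.

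Without infection the mutants already differed from WT. Higher in mock-treated wrky72-1 and wrky72-2 were STZ by 2.23 and 2.21, AT4G29780 by 2.02 and 2.11, AT1G11210 by 1.95 and 1.92, AT2G19970 by 1.94 and 1.91, AT2G22880 by 1.90 and 1.74, WRKY53 by 1.88 and 1.81, AT3G10930 by 1.74 and 1.87 and AT1G05575 by 1.72 and 1.95. Lower in the mutants were AT1G43590 (-2.15 and -2.09), AT3G48640 (-2.10 and -2.05), CHI (-1.85 and -1.85), AT1G26390 (-1.75 and -1.51), AT4G28290 (-1.59 and -1.28) and AT1G19960 (-1.54 and -1.58), and in wrky72-2 the osmotin gene OSM34 (-1.52). In wrky72-1 1186 probe sets were higher and 1131 lower, and in wrky72-2 1198 and 992. The larger side turned with quantile normalisation applied again (1096 and 1219, and 1084 and 1097) and, in wrky72-1, with array medians set equal (1035 and 1234). The GAPDH difference between the 3' and 5' sets was higher in mock WT, at 0.44 to 0.50, than in mock mutants, at 0.26 to 0.35 (exact permutation p = 0.0119, two-sided, not adjusted). That p is the smallest that 84 splits can give. Under infection the same test gave 0.0833 for GAPDH. For actin and ubiquitin it gave 0.19 and 0.345 under mock and 0.202 and 0.107 under infection. For wrky72-2 array weights gave 3506 probe sets, and leaving out replicate 1 of mock wrky72-2 gave 1450.

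Early immune signalling genes were higher in mock-treated mutants, 10 of 25 up in wrky72-1 (mean 0.48, camera adjusted p = 4.1e-12 and 0.00021 with an estimated correlation) and 13 in wrky72-2 (0.47, adjusted p = 3.5e-13 and 0.00014). Salicylate and systemic immunity genes were lower, with 4 down and 1 up in wrky72-1 (mean -0.35, adjusted p = 0.00045 and 0.017 with an estimated correlation) and 4 down in wrky72-2 (-0.36, adjusted p = 0.0006 and 0.019). The planned salicylic acid list had 2 of 4 members down in each mutant, 2 in wrky72-1 and 3 in wrky72-2 adjusted over the list alone, and means of -0.35 and -0.36, called with the preset correlation (0.0032 and 0.0048) and not otherwise (adjusted p = 0.077 in each with an estimated correlation). The cold and drought list was higher in wrky72-1, with COR47 at 1.05 and LTI30 at 1.11 (mean 0.59, adjusted p = 0.00024 and 0.041 with an estimated correlation), and in wrky72-2, with COR47 at 1.1 and LTI30 at 1.35 (mean 0.64, adjusted p = 0.0001, adjusted p = 0.051 with an estimated correlation). In each mutant 3 of its 4 members were up, also adjusted over the list alone. The WRKY list was higher in wrky72-1, with 2 of 7 up over all probe sets and 4 adjusted over the list alone (mean 0.45, 0.0022 and 0.041 with an estimated correlation), and in wrky72-2, with 3 and 4 (mean 0.37, adjusted p = 0.005, adjusted p = 0.072 with an estimated correlation).

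Under infection more probe sets differed from WT than under mock, an order that turned under some settings. WRKY53 was higher by 1.93 in wrky72-1 and 1.98 in wrky72-2, AT3G02480 by 1.85 and 1.96, AT1G64380 by 1.88 and 1.46, the plastid gene rpl22 by 1.66 and 1.47, the ubiquitin ligase gene PUB19 by 1.58 and 1.69 and AT2G39920 by 1.42 and 1.64. AT4G27652 was lower (-2.45 and -2.49), as were the transcription factor gene UPB1 (-1.99 and -2.07), AT2G39980 (-1.96 and -2.16), AT3G21670 (-1.93 and -1.81) and AT5G62280 (-1.59 and -1.95). Leucine breakdown genes were higher, 6 of 8 in each mutant, with means of 0.37 (adjusted p = 1.4e-05 and 0.013 with an estimated correlation) and 0.33 (0.00031 and 0.022), and 5 and 3 of 20 beta-glucosidases were, with means of 0.21 (0.003 and 0.027) and 0.21 (0.0029 and 0.022). In wrky72-1 1788 probe sets were higher and 2030 lower, and in wrky72-2 1333 and 2023. With quantile normalisation applied again these were 1928 and 1870, so the larger side turned, and 1598 and 1736. For wrky72-2 a fit of only the groups compared called 1895 under infection against 2951 under mock, and array weights 3246 against 3506. For wrky72-1 the covariate of hybridisation controls gave 2272 against 2349. The control sets for poly(A) spikes were higher in WT than in mutant arrays by 0.69 under mock and 0.30 under infection (exact permutation p = 0.0238 and 0.0119, two-sided). Outside replicate 3 of mock WT their means were 4.47 to 5.08, no higher than the median probe set, so they may be background there. Replicate 3 of mock WT, at 6.84 against 5.08 and 5.03 in the other mock WT arrays and 4.92 to 5.03 in mock mutants, carried most of the mock difference, which was 0.09 without it. The hybridisation controls were higher in WT by 0.36 under infection (exact permutation p = 0.0238). The p values of control sets were not adjusted for the number of such tests.

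Differences from WT were shared by the mutants. Both mutants had 835 probe sets higher and 763 lower under mock, where independence would give 62.5 and 49.3, and 1027 higher and 1522 lower under infection, where it would give 105 and 181. Across probe sets, the mutants' differences from WT correlated at r 0.861 under mock and 0.871 under infection, and their interactions at 0.801. Because the same WT arrays serve both mutants, unchanged simulated groups gave 0.50, 0.502 and 0.501, so part of the correlation comes from that design. The covariance exceeded the simulated one by 0.0425, 0.0559 and 0.0735. In all 4 comparisons of a mutant with WT, 163 probe sets were higher and 296 lower.

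Few or no differences between the mutants were detected. With limma, 0 probe sets differed between wrky72-2 and wrky72-1 under mock, with 1647 (7.24%) at an unadjusted p under 0.05, and 0 under infection, with 1919 (8.44%). The difference between their responses gave 0 calls, with 2486 (10.9%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.179. The genes with the lowest p did not pass: under mock AT1G75990 (0.39), AT4G27380 (0.56), AT1G03740 (0.46), AT1G52810 (-0.46), AT3G24150 (-0.47) and AT1G53760 (-0.43), under infection AT4G03730 (0.35), MYC4 (-0.50), AT4G01860 (-0.46) and AT1G05410 (-0.58), and in the response AT1G49960 (0.82 ± 0.14), MYC4 (-0.69 ± 0.13) and AT1G05410 (-0.81 ± 0.15). On simulated data the same tests recovered 83.6% of changes of 0.5 between the mutants under mock and 29.9% between their responses. Without replicate 1 of infected wrky72-2, 36 probe sets were called under infection and 7 in the difference between the responses. With a replicate block for the infected mutants, whose numbers may pair the arrays, 6 were called under infection and 8 in the difference between the responses.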

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

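The tests of the hybridisation and labelling controls, of the share of larger mock differences and of early immune genes under mock, the covariate fits, the comparison of 3' and 5' controls, the response size over jointly chosen probe sets, the added gene lists and the list tests between genotypes were chosen only after the result was seen.

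The arrays of WT stood apart from those of both insertion lines in both treatments, and 2995 probe sets had a different response in the mutants, 2488 in wrky72-1 and 2155 in wrky72-2. A batch that moved the spiked hybridisation controls would put all WT arrays outside the range of the mutant arrays. Outside it lay 3 of 6 WT arrays, all infected, and 0 under mock (WT minus mutants 0.09, exact permutation p = 0.429, two-sided, and infected 0.36, p = 0.0238, with 84 splits each). Yet 2317 and 2190 probe sets differed under mock, which argues against such a batch as the cause of the mock differences. Under infection it stays open. A batch that leaves the mean of these controls unmoved was not tested. The control sets for poly(A) spikes, which are meant to be added before labelling, lay outside that range in 5 of 6 WT arrays (mock 0.69, exact permutation p = 0.0238, and infected 0.30, p = 0.0119, not adjusted). Under mock 1 array at 6.84 carried most of the difference, and 0.09 was left without that array. In all other arrays these sets had means of 4.47 to 5.08, no higher than the median probe set. Signal that low may be background, so these values do not decide on a labelling batch. A labelling batch may contribute, and because no labels give one it cannot be told apart from genotype. Loss of WRKY72 in both lines, the biological explanation that the design gives, stays open with it. In simulation, independent noise in the shared WT arrays alone gave a mean of 0, 0 and 0.05 shared calls, so noise of that kind does not account for the shared differences. The simulation held no shift common to the WT arrays and cannot show what such a shift would give.

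A second pattern concerns the 700 probe sets that rose in WT and rose less or fell in the mutants, such as STZ (interaction -2.81), AT3G10930 (-2.86), AT4G27657 (-2.81) and AT4G27652 (-2.72). Their choice favours probe sets with a high level in mock mutants (median difference 0.35), and for 56.4% of them the mutants differed from WT by more under mock than under infection, so this share does not decide whether a higher starting level is the cause. Early immune genes were higher than other genes in both mock mutants, with 1.58e-13 as the larger camera p of the mutants, and 6.56e-09 over the 16 of 25 that are not in this set. These differences had been seen before the test was chosen, so it restates them and does not decide the question. The hypothesis that a raised level in untreated mutants lies behind the pattern stays open, and whether such a level comes from the genotype or from the growth or handling of those plants was not tested.

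The third pattern is the difference in response between WT and mutants, which gave the mutants larger medians over raised probe sets chosen in the other mutant (by 0.0955 in wrky72-2 and 0.189 in wrky72-1), smaller gaps where they were chosen jointly (0.0341 and 0.110) and no common direction where they were chosen in WT (0.56 against 0.61 and 0.53), a choice that favours WT. Slopes on WT over the jointly chosen raised sets were 1.05 in wrky72-1 and 0.972 in wrky72-2, so a larger response as such is not claimed. The hybridisation controls were lowest in infected mutant arrays, at 8.54 in wrky72-1 and 8.63 in wrky72-2 against 8.94 in infected WT and 8.92 to 9.09 in mock groups. With their mean as a covariate, 74.99% of the interaction calls were made again (2246 of 2995), after a first form of the test that counted all calls (2488, or 83.1%) had passed the bound set for excluding it, so a contribution of the spiked signal stays open. With the GAPDH difference between 3' and 5' controls as a covariate 53.9% were, and that difference had an interaction of 0.35 ± 0.11 for GAPDH, 0.01 ± 0.08 for actin and -0.0346 ± 0.0717 for ubiquitin, so a contribution of RNA integrity cannot be told apart from a change in GAPDH itself. Over the 2995 probe sets called without a covariate, the median size was 0.558 without one, 0.554 with the hybridisation controls and 0.551 with GAPDH. The median standard error rose from 0.126 to 0.138 and 0.163, and calls can be lost to that larger error. With the hybridisation covariate, the gaps in median over sets chosen in a mutant were 0.993 to 1.18 times those without it. The model holds a mean for each group, so a covariate's slope came only from differences between arrays within a group. Whether that slope holds between groups was not tested. These values thus do not decide whether spiked signal or RNA integrity is the whole cause.

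Splits of the arrays into groups of the same sizes, with the real grouping counted as 1 of them, show how far chance can be excluded. Of 100 splits, 1 gave as many probe sets for the interaction of both mutants (real 2995, highest other 2904), 2 for wrky72-1 (2488, highest other 3576) and 2 for wrky72-2 (2155, highest other 3134). A random assignment of arrays to genotypes thus seldom gave such counts. The splits also break up the difference between genotypes, so they cannot exclude chance for the interaction apart from that difference. The higher splits exchange the genotypes in the infected arrays alone and so carry the difference between genotypes, a structure of the samples. For the probe sets called in WT and in neither mutant, 34 of 100 splits gave as many (real 1265, highest other 2527), so chance cannot be excluded for that count. For the difference between the mutants' responses all 100 did (real 0, highest other 24), which any split must when the real count is 0, so nothing follows from it. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real counts were 7378, 10308 and 8501 for the responses of WT, wrky72-1 and wrky72-2, 2317 and 2190 for the mutants against WT under mock and 3818 for wrky72-1 under infection, each reached in 1 split with a highest other of 0. For wrky72-2 under infection the real count was 3356, reached in 1 split, with a highest other of 2. Between the mutants the real count was 0 under mock (highest other 0) and 0 under infection (highest other 57), with limma, against 1647 and 1919 at an unadjusted p under 0.05. All 10 splits reached a count of 0, as they must.

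Among single genes the response was tested to differ upwards in the mutants for CHI (2.12), AT3G02480 (2.04), AT1G26390 (2.04), AT2G44240 (1.66) and BGLU46 (1.53), and downwards for AT3G21670 (-2.85). Among gene lists it was higher for salicylate and systemic immunity (mean 0.45), leucine breakdown (0.30), autophagy (0.28) and beta-glucosidases (0.20), and lower for cold and drought (-0.79), xyloglucan endotransglucosylases (-0.52), early immune signalling (-0.42), dehydration proteins (-0.39), jasmonate (-0.35), glutathione S-transferases (-0.22) and expansins (-0.22). With an estimated correlation between genes, the lists of autophagy (adjusted p = 0.35), beta-glucosidases (0.0549), dehydration proteins (0.0851), glutathione S-transferases (0.0633) and expansins (0.139) did not pass. Outside the tested probe sets, 3 of the 64 Affymetrix controls, the 5' and middle sets of the plant's own GAPDH and no 3' set, had a lower response in the mutants (-0.65, -0.41 and -0.58; adjusted p = 0.0312, 0.0312 and 0.0356), and 0 of the 18 hybridisation controls did.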

How the results depend on the processing

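The covariate settings, the replicate block for infected mutants, the fit without their replicate 3, the list means under rescaling and the size over jointly chosen probe sets were chosen only after the result was seen. Over 36 alternatives, 0 of 932 named gene and contrast pairs reversed where they had a value, and without the lowest 30% of probe sets 44 had none. A turned sign counted only where the pair was called. Settings that change only the threshold, the variance estimate or the probe sets tested cannot turn a sign, so this count says little about them. Calls were lost for 458 pairs at a log2 change of at least 1, 144 at an adjusted p under 0.01, 161, 142 and 127 without replicate 1, 2 or 3, 92 and 85 with the GAPDH and hybridisation covariates, and at most 63 elsewhere. The direction of the response size turned for slopes over lowered sets (0.967 and 0.982, against 1.03 and 1.12 for raised sets). Under rescaling the larger side of some splits turned too. With medians set equal these were the WT response (3154 up, 6228 down, reported 3973 and 3405) and wrky72-1 against WT under mock (1035 and 1234, reported 1186 and 1131). With quantile normalisation again these were the WT response (3315 and 4047), both mutants under mock (1096 and 1219; 1084 and 1097, reported 1198 and 992) and wrky72-1 under infection (1928 and 1870, reported 1788 and 2030). Lists whose mean turned sign had not passed. Over probe sets called in the mean of the WT and mutant responses the differences in median shrank to 0.0341 and -0.0726 for wrky72-2 and to 0.110 and -0.107 for wrky72-1, where the choice does not rest on a mutant alone. Elsewhere the counts named here left the range of 1.5 times the reported count, or the difference in median response moved (reported 0.0955 for sets raised and -0.144 for sets lowered in wrky72-1, 0.189 and -0.198 for wrky72-2); weak signal over background limits small changes.

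A log2 change of at least 1 left 1080, 1615 and 1488 probe sets for the responses of WT, wrky72-1 and wrky72-2. It left 308, 376 and 338 for the interactions of both mutants, wrky72-1 and wrky72-2, 155 and 179 for wrky72-1 against WT (mock, infected), 141 and 160 for wrky72-2, 236 called in WT alone, overlaps of 124 (mock) and 256 (interactions), and sizes of 0.176, -0.495, 0.338 and -0.470. An adjusted p under 0.01 left 1712, 1327 and 1144 for the interactions, 1294 and 2329 for wrky72-1 against WT, 1230 and 1929 for wrky72-2, overlaps of 958 and 840, and a size of -0.204 over sets lowered in wrky72-1. Stricter thresholds lower counts of calls by construction. The count in WT alone is an exception, because the limit also applied to the mutants and so can add probe sets. Of those called in WT alone at the reported threshold, 26 reached a log2 change of 1 in WT. Probe sets with 1 gene are fewer to test, and they gave 3819, 5555 and 4468 for the responses, 1332, 1057 and 931 for the interactions, 1117 and 1844 for wrky72-1 against WT, 1015 and 1623 for wrky72-2, 681 in WT alone, and overlaps of 733 and 623.

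With the hybridisation controls as a covariate the response of wrky72-1 was 6728, its interaction 1610 and wrky72-1 against WT under infection 2272. Over sets chosen again with the covariate, sizes were -0.244 (lowered in wrky72-1), 0.237 and -0.250 (raised and lowered in wrky72-2). Over the sets chosen without it, the absolute sizes were 0.143, 0.224 and 0.230 in that order. With the GAPDH difference as a covariate the size over sets raised in wrky72-2 was 0.253, and 1 probe set was called between the mutants under infection and 1 between their responses. With medians set equal sizes were -0.0330 (lowered in wrky72-1) and 0.229 (raised in wrky72-2). Array weights gave 3506 for wrky72-2 against WT under mock and 1 between the mutants under infection, with the lowest weight, 0.291, on replicate 3 of infected wrky72-2. A fit of only the groups compared gave 1895 for wrky72-2 against WT under infection. In WT, fry called 5 planned lists against 3. The count in WT alone became 645 with the mutants' adjusted p over 0.2, 3024 with their log2 change under 0.5, and 2337 with wrky72-1 in the place of WT. For the settings of this paragraph the cause was not tested.

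Leaving out arrays, the interaction of both mutants ranged from 1537 to 3304, of wrky72-1 from 1180 to 3038 and of wrky72-2 from 958 to 2319. For wrky72-1 against WT the range was 1092 to 2739 under mock and 2278 to 4344 under infection, and for wrky72-2 997 to 2589 (1450 without replicate 1 of mock wrky72-2) and 2053 to 3489. The difference between the mutants' responses ranged from 0 to 7 and the mutants under infection from 0 to 36, both highest without replicate 1 of infected wrky72-2. Called in WT alone were 838 (without replicate 2 of infected WT) to 1504. Overlaps were 788 to 1882 (mock) and 689 to 1656 (interactions), and sizes -0.204 to -0.114 (lowered in wrky72-1), 0.165 to 0.230 and -0.249 to -0.176 (raised and lowered in wrky72-2). The lowest counts mostly came from leaving out a replicate of all 6 groups, which are then smaller. Over all groups replicate numbers did not pair the samples (7 of 45 pairs with r above 0.1, consensus correlation -0.0205). They may pair infected wrky72-1 with infected wrky72-2, groups that were picked on these correlations. A replicate block for these gave 6 calls between the mutants under infection and 8 between their responses, where 0 and 0 were reported, and moved no other count by over 1.5 times. With the replicate block over all groups 7351 probe sets were called in WT, 2924 for the interaction and 1233 in WT alone.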

Other observations

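The genes in this part were singled out after their values were seen, and the tests of added lists were likewise chosen only after the result was seen; the test of chloroplast transcripts was not.

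Some transcripts differed from WT in both treatments. A probe set to which the probe table gives no gene was at 10.60 ± 0.10 in mock and 10.26 ± 0.10 in infected WT, at 7.17 and 5.86 in wrky72-1 and at 7.03 and 5.84 in wrky72-2, so it was lower by -3.43 and -3.57 under mock and -4.40 and -4.42 under infection. AT1G43590 was lower in the mutants in both treatments (-2.15 and -2.09 under mock, -1.51 and -1.63 under infection; interaction 0.55 ± 0.14, adjusted p = 0.013), as was AT3G48640 (-2.10 and -2.05, -1.49 and -1.52). WRKY53 was higher in both treatments (1.88 and 1.81, 1.93 and 1.98) while its response did not differ (interaction 0.11 ± 0.14; adjusted p = 0.74), and AT2G19970 was higher too (1.94 and 1.91, 1.46 and 1.63).

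Several genes fell in the infected mutants and did not pass in WT. The homeobox gene HAT2 had changes of -0.98 ± 0.08 and -0.89 ± 0.08 in wrky72-1 and wrky72-2 against 0.13 ± 0.08 in WT (interaction -1.07 ± 0.10). The expansin-like EXLA1 changed by -1.28 and -1.64 against 0.11 ± 0.09, EXPA8 by -1.08 and -1.08 against -0.16 ± 0.10, and the plastid calcium sensor gene CaS by -1.08 and -0.95 against -0.20 ± 0.09 (interaction -0.82 ± 0.11). The sucrose transporter gene SWEET11 rose in WT (0.26 ± 0.08) and fell in the mutants (-0.45 and -0.39; interaction -0.68 ± 0.09). In the secretory pathway SEC6 (0.81 ± 0.19) and KEU (0.63 ± 0.16) had a higher response in the mutants, while the 15 listed genes of exocytosis were not called as a list (mean 0.18; adjusted p = 0.15).

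Among probe sets with no listed gene, the highest responses in WT were 4.44 ± 0.16 and 3.75 ± 0.09 and the lowest -2.26 ± 0.16 and -2.11 ± 0.11.

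Chloroplast-encoded transcripts varied between arrays of the same group, most in infected wrky72-2, where their mean had an SD of 0.32. A candidate explanation is that RNA without a poly(A) tail was carried into labelling to a differing extent. Within-group deviations of the mean of 69 chloroplast-encoded probe sets correlated with those of the 25S rRNA control over the 18 arrays at r 0.776 (permutation p = 0.00479) and rho 0.736 (p = 0.0059), and at r 0.698 without replicate 3 of infected wrky72-2 and of infected wrky72-1. This was the only relation of its kind computed, so no adjustment applies. It is consistent with such carry-over as a hypothesis, and other causes of shared variation were not tested.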
